A study of Homo sapiens with 8 samples.

How the data were processed

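Gene expression was measured by RNA sequencing in primary human lung fibroblasts of 1 donor. Per the labels' protocols, RNA was taken with Trizol and made into Illumina TruSeq stranded libraries after depletion of ribosomal RNA. There were 8 libraries, 1 for each combination of plasmid (FLIL33 or the non-coding NULL), stimulation (TGF-beta or none) and time after stimulation (24 h or 48 h).

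The authors deposited 1 table of raw counts per gene symbol, with 1 column per library and 23682 genes, and these counts carry no normalization. Per the submitters' processing notes, STAR, HTSeq 0.6.1p2 and DESeq2 were used with the human builds hg19 and GRCh37. What each of these tools did, the counting mode, the strand setting and the annotation are not given in the sources used here. Reads from overlapping or antisense genes, from near-identical copies such as AKR1C1 and its relatives, from the HLA genes and from the histone genes may therefore be split or shared between symbols, and their values are uncertain. No coordinates are given, because the reference used here is a later build. The table named no feature other than genes, and every column was matched to a library by its name. Totals ran from 12397112 to 15605639 counts per library.

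Tests were run in R 4.3.3 with edgeR 4.0.16 on the deposited counts. Genes passed edgeR's filterByExpr with a minimum count of 10 over the 4 combinations of plasmid and stimulation, which left 13368 genes and removed 10314. Library sizes were scaled by TMM. The quasi-likelihood test used all 8 libraries and a model with time, plasmid, stimulation and the plasmid by stimulation interaction, which leaves 3 residual degrees of freedom. The differences of the TGF-beta effect and of the FLIL33 effect between times came from models with the interaction of stimulation or plasmid with time and the remaining factor, also with 3 residual degrees of freedom. There were 11 comparisons, each adjusted over its genes by the Benjamini-Hochberg method with a threshold of 0.05, and adjusted p-values are edgeR's unless another tool is named. No combination had a replicate culture. In the first model the p-values thus measure only the departure from a time effect common to all combinations of plasmid and stimulation. Culture, library and time-by-treatment differences are mixed in it. In the models of the differences between times they measure the departure from a common effect of the remaining factor. That spread also holds the plasmid by stimulation difference. No p-value says anything of other donors. Values after ± are standard errors of the log2 change.

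CPM are as given by edgeR for the TMM-scaled library size, and log2 CPM used a prior count of 2. Intervals of single counts are exact Poisson intervals at 95% and cover counting error only. There were 27 gene lists, of which 25 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation and with fry, for 4 comparisons, adjusted over the lists within a comparison. fry tests whether the genes of a list move on balance one way and does not compare them with other genes. With an estimated correlation no list passed in any comparison, and the lowest adjusted p was 0.0697, for the early targets of TGF-beta. A failure in that setting therefore does not tell one list from another. The 13 mitochondrially encoded genes of 1 list had no entry in the table, and the mesothelial list had 2 tested members.

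The design, the tests, the gene lists, the naming rule and the other settings listed below were fixed before the data were examined. Named were IL33, and for the TGF-beta and FLIL33 effects the 10 genes with the largest change in each direction among those past the threshold, with a mean log2 CPM of at least 2 and 1 sign in all 4 matched pairs. For the other comparisons the 5 largest were named. Where fewer passed, the 5 genes with the smallest p were given as values. From each list the 4 members with the smallest p could be named, and CTGF, ACTA2, COL1A1, COL1A2 and COL3A1 were always given. Some genes that these rules name are not reported here. The genes called in the tests of a difference between times had no rule and were named after their values were seen. Sex-linked marker genes were not examined by library.

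The other settings were the size factors of DESeq2, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom, an additive model, a model with no time term, a model with all 2-way interactions, either time alone, IL33 left out, a threshold that also asks for an absolute log2 change of at least 1, and each library left out in turn. The fits of either time alone and with all 2-way interactions leave 1 residual degree of freedom. Their p-values and counts rest on a poorly known spread. A correction for GC content was added after the data were seen. It took the GC content of the longest transcript of each symbol in GENCODE release 29, which gave a value for 12965 of the 13368 tested genes (97.0%). A robust spline with 5 degrees of freedom, refitted 5 times, described each library's trend, which entered the model as an offset.

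The procedure was tested on simulated data with the means, dispersions and library sizes of the 13368 genes, 200 of them changed. For the FLIL33 effect, edgeR recovered 53.7% of the genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold, with 15 false calls. For the TGF-beta effect it recovered 44.8%, 86.6% and 98.5%, with 18 false calls. For the plasmid by TGF-beta interaction it recovered 5.97%, 35.8% and 72.7%, with 8 false calls. For the plasmid by time interaction it recovered 0%, 25.4% and 69.7%, with 7 false calls. In 1 draw with no gene changed there were 3 calls for the FLIL33 effect, 4 for the TGF-beta effect and 0 for the time effect. There were 2 for each of the differences between times and 1 for the plasmid by TGF-beta interaction. A single draw without time or treatment differences does not give the rate of chance calls in the real data.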

Results

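The series asked how lung fibroblasts respond to overexpression of FLIL33, the full-length form of the cytokine and nuclear protein IL-33, to TGF-beta, a growth factor that drives fibroblasts to make matrix, and to the 2 together. Normal human lung fibroblasts from 1 donor were given the FLIL33 plasmid or the non-coding NULL plasmid by electroporation, were stimulated with recombinant human TGF-beta or left unstimulated 24 h afterwards, and were harvested 24 h or 48 h later. Each of the 8 combinations has 1 library, so no value has a replicate at the same time. Library totals ran from 12397112 to 15605639 counts, and 17029 to 18352 genes had at least 1 count in a library. No 2 libraries held the same values, since at most 2.21% of the tested genes had identical counts in any pair of libraries. On log2 CPM of the tested genes, the first principal component (52.6% of the variance) separated the 4 stimulated libraries (29.4 to 38.6) from the 4 unstimulated ones (-37.1 to -28.9). The second (19.4%) separated 48 h (13.9 to 27.7) from 24 h (-24.1 to -16.8), and the third (12.8%) set the unstimulated NULL library of 48 h (-34.7) apart from the FLIL33 libraries of 48 h (18.0 and 18.9).

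IL33 was higher in the FLIL33 library of each of the 4 matched pairs, by modest ratios. In unstimulated cells at 24 h it stood at 46.8 CPM with NULL (634 counts, 95% interval 586 to 685) and 64.0 CPM with FLIL33 (875 counts, interval 818 to 935), a ratio of 1.37. The ratio was 1.40 with TGF-beta at 24 h (36.2 and 50.6 CPM), 1.18 without it at 48 h (45.7 and 54.0 CPM) and 1.82 with it at 48 h (29.2 and 53.1 CPM). The mean log2 change was 0.51 ± 0.09, with an adjusted p of 0.25 in edgeR, so this difference in IL33 did not pass the test over all genes. It passed in 6 of 18 other settings. These include the fit without the NULL unstimulated library of 24 h (adjusted p = 0.0222), no filter (0.000916) and DESeq2 (0.0106). The rest were the fits with all 2-way interactions (3.38e-08) and of the 24 h (5.46e-08) or 48 h libraries alone (0.00746). Each of the latter fits has 1 residual degree of freedom, so its p-value rests on a poorly known spread. With TGF-beta IL33 was lower in 4 of 4 pairs. In the FLIL33 pair of 48 h the difference lay within counting error (54.0 CPM without, interval 50.1 to 58.1, and 53.1 CPM with TGF-beta, interval 49.5 to 56.9). The mean log2 change with TGF-beta was -0.34 ± 0.09, with an adjusted p of 0.0242 in edgeR. That call was lost without the FLIL33 unstimulated library of 24 h (adjusted p = 0.108), the FLIL33 TGF-beta library of 24 h (0.105) or the NULL TGF-beta library of 48 h (0.148).

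**Figure D1:**
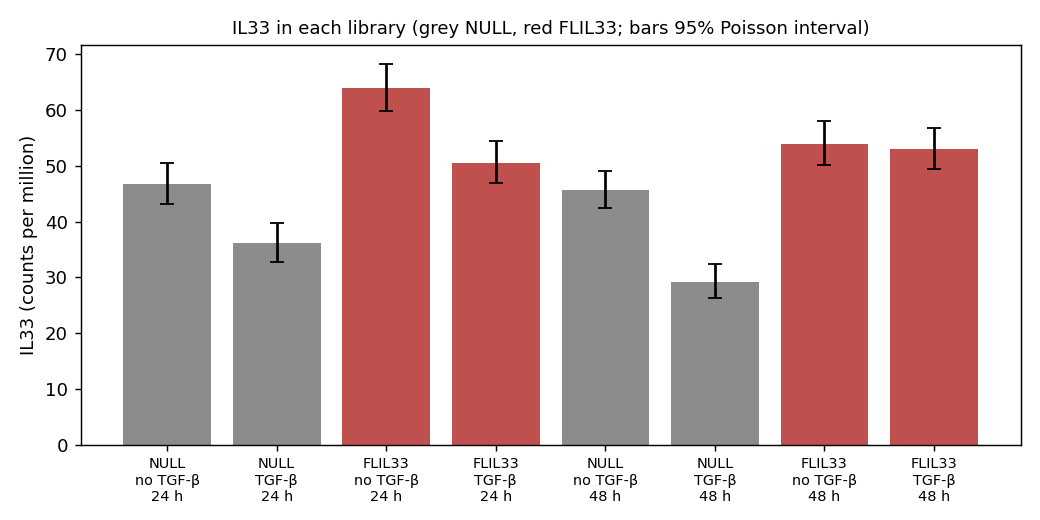
IL33 CPM of each library, grey for the NULL plasmid and red for FLIL33, with exact 95% Poisson intervals that cover counting error only. FLIL33 libraries lie between 50.6 and 64.0 CPM and NULL libraries between 29.2 and 46.8 CPM.

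TGF-beta raised matrix and contractile genes in these cells. Of 13368 tested genes, 1874 rose and 1616 fell (mean over plasmids, 4 libraries against 4), 993 of them by at least 2-fold, and 3426 of the 3490 moved the same way in all 4 matched pairs. Genes that were close to silent without TGF-beta reached clear expression with it. PRG4, which encodes the joint lubricant lubricin, went from 0 to 0.323 CPM without TGF-beta to between 17 and 40.4 CPM with it. COMP, a cartilage matrix protein, went from 0 to 0.15 CPM to between 5.04 and 16.9 CPM, and AMTN, a mineral-associated matrix protein, from 0 to 0.0751 CPM to between 5.98 and 13.9 CPM. EDN1, the precursor of the vasoconstrictor endothelin-1, rose by a log2 change of 6.34 ± 0.18 (adjusted p = 9.45e-08), and NOX4, a hydrogen peroxide-producing oxidase, by 6.08 ± 0.18 (9.45e-08). The cytokine IL11 rose by 5.78 ± 0.26 (6.62e-07), the insulin-like growth factor binding protein IGFBP3 by 5.55 ± 0.18 (1.3e-07), the transcription factor EGR2 by 5.74 ± 0.24 (4.48e-07) and the melanogenic enzyme TYRP1 by 5.66 ± 0.37 (5.74e-06).

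The genes that fell most with TGF-beta included a regulator of fat storage, a Wnt ligand and a potassium channel. ADH1B, an alcohol dehydrogenase, stood at 7.30 and 2.63 CPM at 24 h and at 147 and 41.8 CPM at 48 h without TGF-beta, and between 0.524 and 1.39 CPM with it. PPARG, the central adipogenic transcription factor, had a log2 change of -2.51 ± 0.17 (adjusted p = 6.98e-06). NOV, a matricellular protein, had -2.89 ± 0.22 (1.43e-05), NPTX1 -2.57 ± 0.10 (3.1e-07), RASL11A -2.92 ± 0.26 (4.28e-05), the potassium channel KCNJ2 -2.49 ± 0.23 (5.12e-05), FER1L6 -2.40 ± 0.24 (9.17e-05) and the Wnt ligand WNT16 -2.21 ± 0.12 (2.39e-06). AKR1C1 had -2.38 ± 0.11 (8.6e-07), and its reads may be shared with close relatives.

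Matrix genes rose as a group. All 33 tested collagens and matrix proteins had positive log2 changes, with a median of 1.57, and 27 rose over all genes tested and 27 adjusted over the list alone. COL1A1 rose by 2.88 ± 0.27, COL5A1 by 2.66 ± 0.12, COL7A1 by 2.68 ± 0.13, COL10A1 by 3.14 ± 0.15, COL3A1 by 1.28 ± 0.11 and COL1A2 by 1.07 ± 0.10. Of 20 tested genes for collagen processing and crosslinking, 15 rose (16 adjusted over the list alone), among them the lysyl oxidase LOX (1.92 ± 0.16), the lysyl hydroxylase PLOD2 (1.63 ± 0.13), the collagen chaperone SERPINH1 (1.04 ± 0.10) and the collagen receptor subunit ITGA11 (3.77 ± 0.34). Of 23 tested proteases and inhibitors, 13 rose and 5 fell (the same counts adjusted over the list alone), with ADAM12 at 3.31 ± 0.12 and the inhibitor TIMP3 at 1.87 ± 0.11. By camera the 3 lists were higher than other genes, with adjusted p-values of 6.39e-18, 4.97e-07 and 0.00194. None of these held with the correlation estimated from the libraries, which gave adjusted p = 0.201 with an estimated correlation for matrix, adjusted p = 0.325 with an estimated correlation for processing and adjusted p = 0.201 with an estimated correlation for proteases. By fry all 3 moved up on balance (0.00362, 0.0141 and 0.00102).

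Direct TGF-beta targets and contractile genes rose too. Of 26 tested early targets of TGF-beta and SMAD, 23 rose and 1 fell (24 and 1 adjusted over the list alone), including the matricellular protein gene CTGF (3.57 ± 0.11) and PMEPA1, a feedback inhibitor of the pathway (4.60 ± 0.15). Of 26 tested contractile and myofibroblast genes, 19 rose and 1 fell (20 and 1 adjusted over the list alone), among them ACTA2, the smooth muscle actin that marks myofibroblasts (2.91 ± 0.24), the calponin CNN1 (2.33 ± 0.14) and the tropomyosin TPM1 (3.17 ± 0.22). The actin gene ACTC1 went from between 0.0645 and 0.885 CPM to between 13.8 and 59.1 CPM. The lists had camera adjusted p-values of 5.08e-17 and 1.44e-08. They had adjusted p = 0.0697 with an estimated correlation for early targets and adjusted p = 0.268 with an estimated correlation for contractile genes. Of 20 tested pathway components, 8 rose and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.148, up on balance by fry at 0.00519). The receptor TGFBR1 rose by 1.49 ± 0.10, while SMAD3 and the co-receptor TGFBR3 had log2 changes of -1.48 ± 0.13 and -1.04 ± 0.09. Of 10 tested BMP and ID genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.234, up on balance by fry at 0.00519), with ID3 at 2.38 ± 0.15 and HEY1 at 2.13 ± 0.33.

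**Figure D2:**
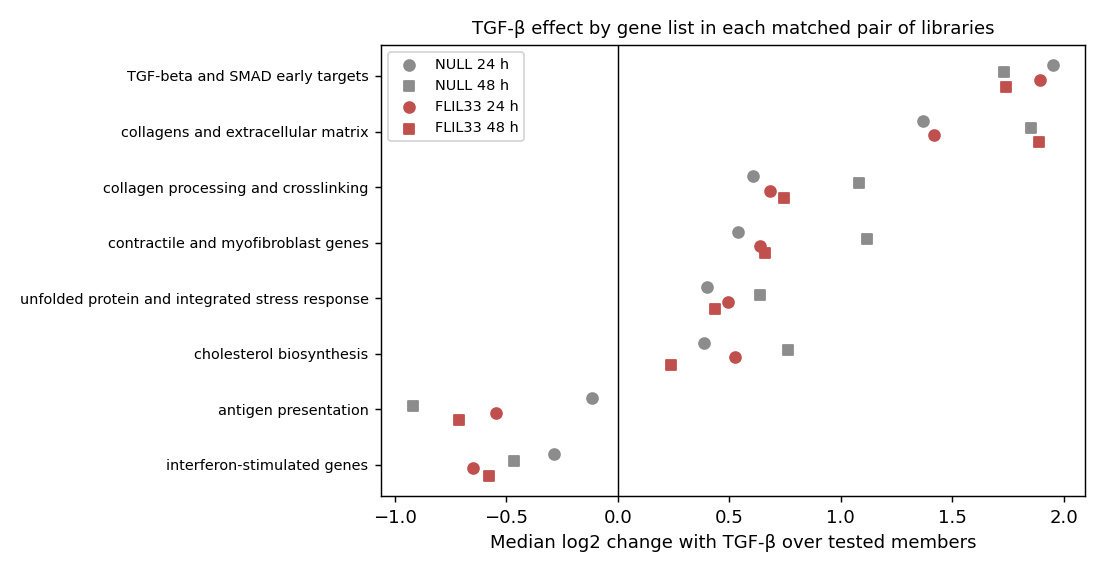
Median log2 change with TGF-beta over the tested members of 8 gene lists, with 1 point for each matched pair of libraries (grey NULL, red FLIL33; circles 24 h, squares 48 h). The medians of early targets lie between 1.73 and 1.95 and those of matrix genes between 1.37 and 1.89, and those of interferon-stimulated genes between -0.65 and -0.29.

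Stress response and cholesterol synthesis genes rose with TGF-beta. Of 25 tested genes of the unfolded protein and integrated stress response, 18 rose (19 adjusted over the list alone). The leading members were ATF4, the main transcription factor of the integrated stress response (0.94 ± 0.08), the asparagine synthetase ASNS (2.07 ± 0.13), the serine synthesis enzyme PSAT1 (2.34 ± 0.20) and CHAC1 (1.93 ± 0.15). Of 22 cholesterol synthesis genes 16 rose (19 rose and 1 fell adjusted over the list alone), including SQLE (0.98 ± 0.09) and HMGCS1 (0.80 ± 0.12). Of 25 glycolysis and hypoxia genes 12 rose and 2 fell (16 and 2 adjusted over the list alone), with VEGFA at 1.17 ± 0.13. Camera adjusted p-values were 1.96e-08, 2.52e-06 and 0.00981. They became adjusted p = 0.201 with an estimated correlation for the stress response, adjusted p = 0.342 with an estimated correlation for cholesterol and adjusted p = 0.498 with an estimated correlation for glycolysis. By fry the glycolysis list did not move on balance (0.0979).

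Most interferon-stimulated, antigen presentation and lipid droplet genes fell with TGF-beta, as did some genes of the list for IL-33 receptor signalling and type 2 responses. Of 42 tested interferon-stimulated genes, 25 fell and none rose (26 fell adjusted over the list alone), with a median log2 change of -0.53. RSAD2, an antiviral enzyme, had -1.45 ± 0.13, GBP4 -1.68 ± 0.13, the transcription factor IRF1 -1.02 ± 0.09 and OAS2 -0.93 ± 0.09. Of 13 tested antigen presentation genes 7 fell (7 adjusted over the list alone), including the MHC class II regulator CIITA (-1.60 ± 0.36) and HLA-DMA (-1.32 ± 0.25). Of 13 lipid droplet genes 8 fell and 1 rose (the same counts adjusted over the list alone), including the lipid droplet coat protein PLIN2 (-1.32 ± 0.10) and the fatty acid carrier CD36 (-2.05 ± 0.33). Of 15 tested genes of IL-33 receptor signalling and type 2 responses 5 fell and 1 rose (6 and 1 adjusted over the list alone). The IL-1 receptor gene IL1R1 had -1.02 ± 0.11 and the cytokine TSLP -0.63 ± 0.12. None of the 4 members with the smallest p (IL1R1, IRAK2, IL13RA2 and TSLP) encodes a chain of the IL-33 receptor. Camera adjusted p-values were 1.8e-07, 0.000266, 0.0293 and 0.0309. They became adjusted p = 0.201 with an estimated correlation for interferon, adjusted p = 0.302 with an estimated correlation for antigen presentation, and adjusted p = 0.268 with an estimated correlation for each of the lipid and IL-33 receptor lists.

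Inflammatory genes went both ways, since of 31 tested members 8 rose and 8 fell (8 and 10 adjusted over the list alone, camera adjusted p = 0.864), with TNFAIP6 at 2.79 ± 0.15 and SOD2 at -1.56 ± 0.09. In the fibroblast identity list 4 of 17 rose and 6 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.632). PI16 rose by 4.12 ± 0.26 and MFAP4 by 1.96 ± 0.10, and SFRP1 had -1.22 ± 0.10. Cell cycle genes stood at a median of -0.11, with 1 of 35 higher and 4 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.148). Of the p53 targets 2 of 20 rose and 6 fell (3 and 6 adjusted over the list alone, 0.064, and 0.0364 after GC correction, down on balance by fry at 0.0115), of the NRF2 targets 2 of 20 rose and 8 fell (6 and 10, 0.409), of the heat shock genes 3 of 15 rose and 2 fell (3 and 3, 0.864), and of the histone genes 2 of 10 rose (2, 0.0596). Of the pericyte and smooth muscle markers 5 of 9 rose and 3 fell (the same counts adjusted over the list alone, 0.148, up on balance by fry at 0.00663), with the smooth muscle coactivator MYOCD at 4.32 ± 0.22. Of markers of other cell types, KRT7 was the 1 of 7 tested epithelial markers that rose (1.92 ± 0.21; 1 adjusted over the list alone, 0.928). None of 6 endothelial markers passed (0 adjusted over the list alone, 0.279), 1 of 5 leukocyte markers rose and 2 fell (2 and 3 adjusted over the list alone, 0.508), and CALB2 rose (1.25 ± 0.27) of the 2 tested mesothelial markers (2 adjusted over the list alone). The 3490 calls became 2105 without the NULL TGF-beta library of 48 h and 2310 without the FLIL33 TGF-beta library of 48 h. Without a time term the count was 1910, and no called gene had the other sign in any setting.

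Antiviral, interferon-stimulated genes were higher in the FLIL33 libraries. MX1, an antiviral GTPase, was the 1 gene of 13368 that passed edgeR's test over all genes (mean over stimulation, 4 libraries against 4). It rose 2.52-fold, a log2 change of 1.33 ± 0.12 (adjusted p = 0.0138), in 4 of 4 pairs, from 324 to 1167 CPM in unstimulated cells at 24 h and from 165 to 367 CPM at 48 h. With TGF-beta, MX1 stood at 302 CPM with NULL and 659 CPM with FLIL33 at 24 h, and at 91.4 and 218 CPM at 48 h. A single call may also be due to chance. Simulated data with no gene changed gave 3 calls in this comparison, but that was 1 draw without the time differences of the real data. Small p-values also belonged to OAS2 (0.75 ± 0.09, adjusted p = 0.0505), OAS3 (1.05 ± 0.13, 0.0527) and OAS1 (0.96 ± 0.13, 0.0697), none of which passed here, though each did in 10 of 19 other settings. These include the fits without the NULL unstimulated library of 24 h (adjusted p = 0.00346, 0.00304 and 0.00304) or of 48 h (0.00155, 0.00091 and 0.000512) and, for OAS3 and OAS1, without the NULL TGF-beta library of 24 h (0.0389 and 0.0429). Of the 20 genes with the smallest p, 12 were members of the interferon list. The other counts were 6 in limma-voom, all 6 of them members, and 40 in DESeq2, 16 of them members, and 1203 genes had an unadjusted p under 0.05 in edgeR, where chance gives 668. They numbered 1283 in limma-voom and 766 in DESeq2.

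All 42 tested interferon-stimulated genes had positive log2 changes with FLIL33, with a median of 0.50, and 33 were positive in every matched pair. Over all genes tested 1 rose, and 33 rose adjusted over the list alone. Camera placed the list above other genes (adjusted p = 1.39e-27), with adjusted p = 0.146 with an estimated correlation, and by fry it moved up on balance (0.0363). Medians in the matched pairs were 0.53 without and 0.32 with TGF-beta at 24 h, and 0.73 and 0.61 at 48 h. The 13 tested antigen presentation genes had a median of 0.32, with 5 higher adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000137, and adjusted p = 0.735 with an estimated correlation). TAPBP stood at 1.02 ± 0.30, CIITA at 1.19 ± 0.37 and HLA-B at 0.45 ± 0.13, none past the test over all genes.

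**Figure D3:**
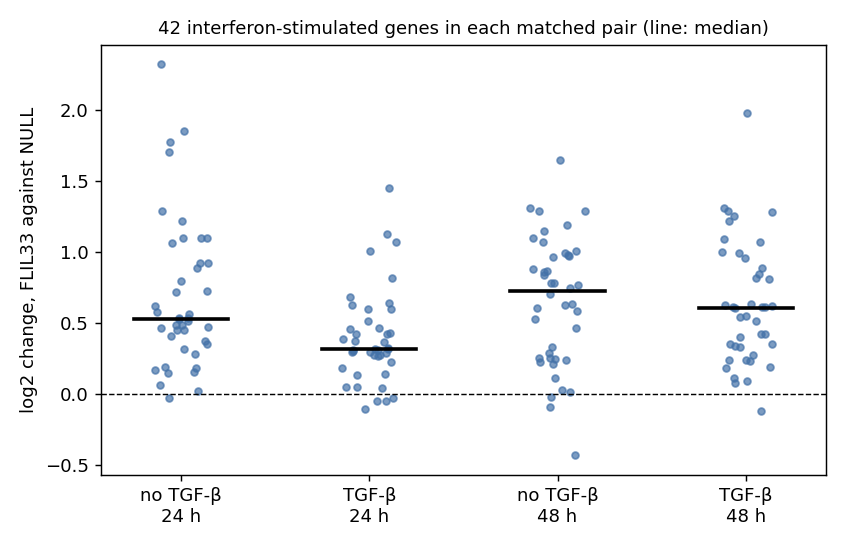
Log2 change with FLIL33 against NULL of the 42 tested interferon-stimulated genes, with 1 point per gene in each of the 4 matched pairs of libraries and a line at the median. The medians are 0.53, 0.32, 0.73 and 0.61 from left to right.

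Matrix and TGF-beta pathway genes lay slightly lower with FLIL33. The 33 matrix genes had a median log2 change of -0.17, with 11 lower adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000497, and adjusted p = 0.755 with an estimated correlation). COL3A1 had -0.57 ± 0.11 (adjusted p = 0.369), LUM -0.39 ± 0.09 (0.412), VCAN -0.43 ± 0.11 (0.412), ASPN -0.68 ± 0.16 (0.405), COL1A2 -0.35 ± 0.10 (0.548) and COL1A1 -0.17 ± 0.25 (0.822). CTGF had -0.16 ± 0.10 (0.588) and ACTA2 -0.21 ± 0.22 (0.746). In the matched pairs the matrix median was -0.27 without and -0.22 with TGF-beta at 24 h, and 0.00 in both pairs at 48 h. After the GC correction described below these were -0.25, -0.22, -0.15 and -0.16 in the same order, and the difference between times was not tested. The pathway components had a median of -0.18 (0 members by either count, camera adjusted p = 0.0155, and adjusted p = 0.735 with an estimated correlation). The fibroblast identity genes had a median of -0.15 (0 members over all genes and MFAP4, at -0.47 ± 0.10, adjusted over the list alone, camera adjusted p = 0.0193, and adjusted p = 0.755 with an estimated correlation). Cell cycle genes had a median of 0.13, with 29 of 35 positive and 0 called by either count (camera adjusted p = 0.00189, and adjusted p = 0.755 with an estimated correlation). By fry the interferon list was the only one of the 25 lists that moved on balance for FLIL33.

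Other lists stayed within the test for FLIL33, with 0 members called over all genes. The 26 early targets of TGF-beta had a median of -0.11 and 0 members by either count (camera adjusted p = 0.135, and adjusted p = 0.735 with an estimated correlation). After GC correction camera placed them lower (0.00782), a setting in which no estimated correlation was tried. Adjusted over the list alone, 5 of 31 inflammatory genes were higher, led by NFKBIA (0.75 ± 0.18) and ICAM1 (0.60 ± 0.15), 1 of 15 IL-33 receptor and type 2 genes (the adaptor MYD88, 0.30 ± 0.08) and 1 of 26 contractile genes (DES, 0.99 ± 0.23). The MX1 call was lost without the FLIL33 unstimulated library of 24 h (adjusted p = 0.252), the FLIL33 TGF-beta library of 24 h (0.264), the NULL TGF-beta library of 48 h (0.145), the FLIL33 unstimulated library of 48 h (0.27) or the FLIL33 TGF-beta library of 48 h (0.478), each of which left 0 calls. The count was 849 without the NULL unstimulated library of 24 h, 14 without that of 48 h and 3 without the NULL TGF-beta library of 24 h, 0 with no time term, 8 in the additive model, all 8 of them interferon list members, 432 with no filter, 464 in the 24 h libraries alone and 1508 in the 48 h libraries alone.

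The FLIL33 effect moved with a trend on GC content in the libraries of 48 h. Relative to the mean of the 8 libraries, the slope of log2 CPM on transcript GC content was 0.198 per 10% GC in the unstimulated FLIL33 library of 48 h and 0.159 in the stimulated one. The NULL unstimulated library of 48 h had -0.137 and the other 5 libraries lay between -0.0638 and -0.00991. Across genes, which are not independent replicates, the Spearman correlation of GC content with the log2 change was 0.475 for FLIL33 in all 8 libraries, 0.0165 in the 24 h libraries and 0.532 in the 48 h libraries. Other comparisons moved with GC content too. The correlation was 0.269 for time, 0.266 for the combination, -0.267 for the plasmid by TGF-beta interaction and 0.0515 for TGF-beta. With the trend taken out 3 genes were called for FLIL33, all higher, and the interferon list kept a median of 0.52. The calls then numbered 1917 for time, with 1448 of the 1600 kept, and 1980 for the combination, with 1586 of the 1675 kept.

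**Figure D4:**
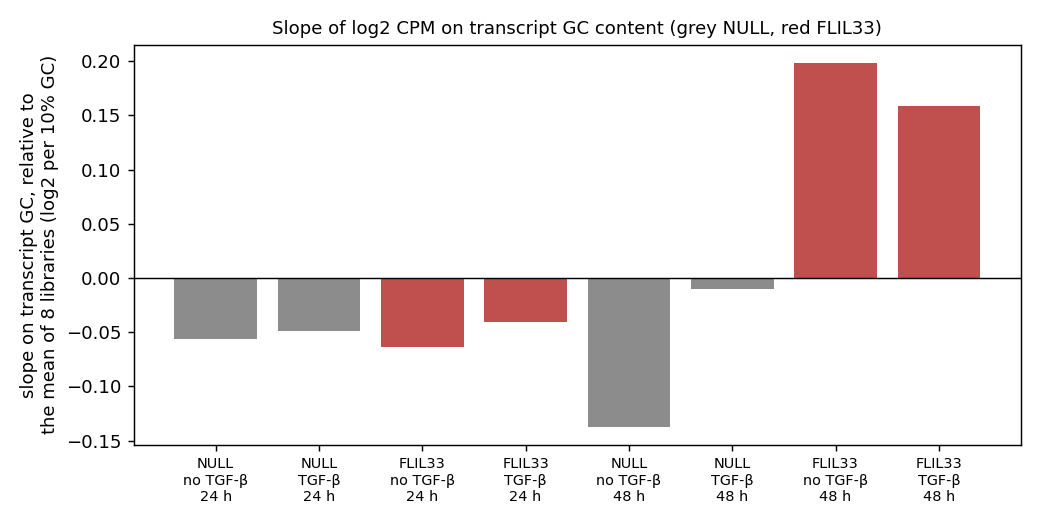
Slope of log2 CPM on transcript GC content of each library, relative to the mean of the 8 libraries, in log2 units per 10% GC (grey NULL, red FLIL33). The FLIL33 libraries of 48 h stand at 0.159 and 0.198 and all others below 0.

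The TGF-beta response looked much alike with either plasmid. In NULL cells 1086 genes rose and 755 fell, and in FLIL33 cells 957 rose and 678 fell (2 libraries against 2 each, with no library in common). Across genes the log2 changes had a Pearson correlation of 0.87 and a Spearman correlation of 0.789. Called in the same direction by both were 805 higher genes, where independent lists of these sizes share 77.7, and 505 lower genes, where they share 38.3. No gene was called in opposite directions. The counts in NULL cells became 842 and 560 without the NULL TGF-beta library of 24 h or of 48 h. Those in FLIL33 cells became 698 and 510 without the unstimulated FLIL33 library of 24 h or of 48 h, and 637 and 537 without the stimulated one of 24 h or of 48 h.

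No gene passed edgeR's test of the plasmid by TGF-beta interaction, which asks whether the TGF-beta effect differed between plasmids. An unadjusted p under 0.05 was found in 121 genes, fewer than the 668 that chance gives. DESeq2 and limma-voom also called 0, with 31 and 110 such genes. The spread of this test also holds differences between times, where 1872 (plasmid) and 973 (TGF-beta) genes had such a p. The test is thus strict, and the lack of calls is weak evidence of a like response. With all 2-way interactions, at 1 residual degree of freedom, 19 genes were called (573 unadjusted). The 5 smallest p-values belonged to genes of several kinds, with the mitochondrial enzyme PCK2 at -1.14 ± 0.24, the amino acid transporter SLC7A5 at -1.04 ± 0.26 and the stress transcription factor DDIT3 at -0.61 ± 0.17. CLDN18 had -3.15 ± 0.80 and SCO2 -1.99 ± 0.58, and each of these 5 had an adjusted p of 1. By camera the stress response list had a smaller TGF-beta effect in FLIL33 cells (median -0.14, 0 members called by either count, adjusted p = 0.00809, and adjusted p = 0.702 with an estimated correlation), with ASNS at -0.80 ± 0.25, CHAC1 at -0.96 ± 0.29 and TRIB3 at -1.06 ± 0.39. The same held for cholesterol synthesis (median -0.17, 0 members by either count, camera adjusted p = 0.0285, and adjusted p = 0.793 with an estimated correlation) and contractile genes (median -0.20, 0 members by either count, camera adjusted p = 0.0285, and adjusted p = 0.763 with an estimated correlation). The 10 BMP and ID genes went the other way (median 0.49, 0 members by either count, camera adjusted p = 0.0136, and adjusted p = 0.702 with an estimated correlation), with ID4 at 2.10 ± 1.12 and SMAD6 at 0.98 ± 0.90. For the first 3 lists the medians of the TGF-beta effect were smaller in FLIL33 cells at 48 h only. At 24 h they were 0.40 in NULL and 0.49 in FLIL33 cells for the stress response, 0.39 and 0.53 for cholesterol synthesis and 0.54 and 0.64 for contractile genes, and at 48 h 0.64 and 0.44, 0.76 and 0.24, and 1.12 and 0.66. By fry no list moved on balance in this test. Without the NULL unstimulated library of 24 h 1 gene was called.

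FLIL33 called 0 genes in edgeR in unstimulated cells alone, with 716 at an unadjusted p under 0.05, and 0 in stimulated cells, with 367. In unstimulated cells DESeq2 called 18 (428 unadjusted) and limma-voom 0 (793), and in stimulated cells DESeq2 called 11 (189) and limma-voom 0 (356). MX1 had a log2 change of 1.48 ± 0.18 without TGF-beta (adjusted p = 0.119) and 1.18 ± 0.17 with it (0.756). Between the 2 effects, which share no library, the Pearson correlation across genes was 0.382. Without the NULL unstimulated library of 24 h the counts were 538 and 6, and without that of 48 h 11 and 6.

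Cells given FLIL33 and TGF-beta together differed from cells given neither in 961 higher and 714 lower genes (2 libraries against 2). The genes that rose most were those of TGF-beta alone. EDN1 rose by 6.69 ± 0.26 (adjusted p = 4.45e-06) and IL11 by 6.21 ± 0.38 (1.52e-05). AMTN, COMP and PRG4 reached 5.98, 5.04 and 17 CPM at 24 h and 12.7, 16.9 and 28.4 CPM at 48 h, from at most 0.0738, 0.129 and 0.323 CPM. Lower were FER1L6 (-2.81 ± 0.34, 0.000788), RASL11A (-2.80 ± 0.35, 0.000843), FGL2 (-2.52 ± 0.42, 0.00418), the integrin subunit ITGB8 (-2.52 ± 0.33, 0.00115) and ADH1B, whose CPM are given with the TGF-beta effect. The 1675 calls became 719 and 405 without the FLIL33 TGF-beta library of 24 h or of 48 h, 2903 and 1064 without the NULL unstimulated library of 24 h or of 48 h, and 482 with no time term.

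Across tested genes, the mean TGF-beta and FLIL33 effects were weakly opposed, with a Pearson correlation of -0.147 and a Spearman correlation of -0.11 over 13367 genes without IL33. Of the 1874 genes that rose with TGF-beta, 33.5% had a positive log2 change with FLIL33, against 56.7% of the genes that fell and 49.2% of the other tested genes. MX1 was the 1 gene called in both, lower with TGF-beta and higher with FLIL33. In the 48 h libraries alone the correlation was 0.0183, and in the 24 h libraries alone -0.197.

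From 24 h to 48 h proliferation and interferon genes fell and matrix genes rose (4 libraries against 4, time after stimulation and time after electroporation moving together). The matrix medians rose more in stimulated than in unstimulated cells. In all, 734 genes rose and 866 fell, 222 of the 1600 by at least 2-fold, and 1561 moved the same way in all 4 pairs. The genes that rose most were the endothelin receptor EDNRB (2.15 ± 0.21, adjusted p = 0.000496), TMEM119 (2.09 ± 0.25, 0.00128), the chemerin gene RARRES2 (2.06 ± 0.22, 0.000781), FER1L6 (2.05 ± 0.24, 0.00113) and the nuclear receptor NR4A2 (1.72 ± 0.16, 0.000496). Among those that fell most were ACTC1 (-1.81 ± 0.19, 0.000699), the oxytocin receptor OXTR (-1.75 ± 0.19, 0.000861), MURC (-1.64 ± 0.25, 0.00354) and ESM1 (-1.63 ± 0.25, 0.00405).

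Of 35 tested cell cycle genes 29 fell (31 adjusted over the list alone), with a median log2 change of -0.62, among them RRM2 (-1.17 ± 0.09), MCM7 (-0.96 ± 0.08) and CDK1 (-0.82 ± 0.07). Of 42 interferon-stimulated genes 31 fell (35 adjusted over the list alone), with a median of -0.75, among them MX1 (-1.49 ± 0.12) and IFIT1 (-1.22 ± 0.09). Of 33 matrix genes 18 rose (21 adjusted over the list alone), with a median of 0.52, among them COL10A1 (1.43 ± 0.14), COL3A1 (0.77 ± 0.11) and the fibronectin gene FN1 (0.66 ± 0.11). The matrix median was 0.12 (NULL) and 0.35 (FLIL33) without TGF-beta, and 0.60 and 0.69 with it. After GC correction these were 0.27, 0.25, 0.55 and 0.68. Of the 33 genes 16 were positive in every pair and 2 negative in every pair. Whether the rise of this list differed with TGF-beta was not tested. Of 20 p53 targets 8 rose (14 adjusted over the list alone), led by the cell cycle inhibitor CDKN1A (0.76 ± 0.09). Camera adjusted p-values were 2.07e-21, 1.34e-16, 2.1e-07 and 5.97e-06. They became adjusted p = 0.198 with an estimated correlation for cell cycle, adjusted p = 0.191 with an estimated correlation for interferon, adjusted p = 0.26 with an estimated correlation for matrix and adjusted p = 0.191 with an estimated correlation for p53.

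Of 10 histone genes 5 fell (8 adjusted over the list alone), of 31 inflammatory genes 10 rose and 1 fell (16 and 2 adjusted over the list alone), with PTGES at 1.36 ± 0.19 and IL24 at 1.84 ± 0.32, and of 20 collagen processing genes 6 rose (12 rose and 1 fell adjusted over the list alone), with PCOLCE at 0.70 ± 0.08. Their camera adjusted p-values were 5.97e-06, 0.000653 and 0.0028. These became adjusted p = 0.198 with an estimated correlation, adjusted p = 0.21 with an estimated correlation and adjusted p = 0.535 with an estimated correlation. The collagen processing median was 0.0014 in unstimulated NULL cells and between 0.37 and 0.53 in the other pairs. Of 25 glycolysis genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), with BNIP3 at -0.88 ± 0.13, and of 17 fibroblast identity genes 4 rose (5 adjusted over the list alone), with MFAP4 at 1.54 ± 0.10. Both had a camera adjusted p of 0.0162, with adjusted p = 0.583 with an estimated correlation for glycolysis and adjusted p = 0.535 with an estimated correlation for identity genes. By fry the collagen processing (0.13), glycolysis (0.197) and identity (0.0837) lists did not move on balance with time. The 1600 calls were 2452, 770, 632 and 468 without the NULL unstimulated, NULL TGF-beta, FLIL33 unstimulated or FLIL33 TGF-beta library of 24 h, and 2443, 775, 658 and 475 without the same library of 48 h.

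The TGF-beta effect differed between times for 1 gene, NTM, which encodes the adhesion molecule neurotrimin. In NULL cells NTM stood at 60.4 CPM without and 121 CPM with TGF-beta at 24 h, and at 30.5 and 227 CPM at 48 h, and in FLIL33 cells at 61.6 and 131 CPM at 24 h and 32.8 and 196 CPM at 48 h. Its TGF-beta effect was larger at 48 h by a log2 change of 1.69 ± 0.16 (adjusted p = 0.0168). Simulated data with no gene changed gave 2 calls in this test. In edgeR 973 genes had an unadjusted p under 0.05, and limma-voom called 1 gene (985 unadjusted) and DESeq2 51 (522). The count was 0 without the FLIL33 TGF-beta library of 24 h, the NULL TGF-beta library of 48 h or the FLIL33 TGF-beta library of 48 h, 1 gene other than NTM without the NULL TGF-beta library of 24 h, 2 without the FLIL33 unstimulated library of 24 h, 4 without the NULL unstimulated library of 48 h and 141 without the FLIL33 unstimulated library of 48 h.

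The FLIL33 effect differed between times for 2 genes, both higher with FLIL33 at 48 h. ENG, the TGF-beta co-receptor endoglin, stood at 188 CPM (unstimulated FLIL33, 48 h) and 189 CPM (stimulated), against 84.6 to 105 CPM in the other 6 libraries, a difference between times of 1.29 ± 0.12 (adjusted p = 0.0138). CSDC2, a cold shock domain RNA-binding protein, stood at 33.3 and 43.3 CPM, against 8.33 to 19.4 CPM, a difference of 1.68 ± 0.20 (0.0492). Simulated data with no gene changed also gave 2 calls in this test. With the GC trend taken out the differences were 0.77 ± 0.12 and 1.10 ± 0.20, both with an adjusted p of 0.147. In edgeR 1872 genes had an unadjusted p under 0.05, limma-voom called 1 gene (1911 unadjusted) and DESeq2 206 (1032), and DESeq2 size factors in edgeR gave 54. The count was 0 without the NULL unstimulated library of either time, the FLIL33 TGF-beta library of either time or the FLIL33 unstimulated library of 48 h, 38 without the FLIL33 unstimulated library of 24 h, and 174 and 698 without the NULL TGF-beta library of 24 h or of 48 h.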

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

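Of the tests in this part, the GC correction, the signs of IL33 and of the interferon medians by pair, the margin asked of the count of genes in the first pattern, the change of interferon genes with time in NULL cells and the count among splits with the same degrees of freedom were chosen after the results were seen.

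The effect of FLIL33 differed between times in ENG (1.29 on the log2 scale) and CSDC2 (1.68), by a test of the difference itself that also made 2 calls on simulated data with no gene changed, and 1872 genes had an unadjusted p under 0.05 where chance gives 668. The FLIL33 libraries of 48 h also carried a GC trend, and ENG and CSDC2 are rich in GC (63.3% and 64.3%). Taking out the trend left 1518 such genes and ended both calls, because the changes shrank, from 1.29 ± 0.12 to 0.77 ± 0.12 and from 1.68 ± 0.20 to 1.10 ± 0.20, while their errors stayed about as large. Part of the pattern moved with the trend. A trend behind all of it cannot be told apart from a change in the FLIL33 response with time, since each combination has 1 library. More than 1500 genes had been set beforehand as the count that would argue against the trend, and 1518 is above that. It is treated as undecided because it passes by less than 2 square roots of the count, a margin chosen after the value was seen. Genes are not independent, so this margin does not measure the spread of the count. Without the margin the count would argue against the trend as the whole cause by the bound set beforehand. It could not exclude the trend, since each combination has 1 library and the correction used 1 transcript per symbol.

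Interferon-stimulated genes were higher in FLIL33 libraries, with a median log2 change of 0.50. The median was 0.52 after GC correction and at least 0.47 when any 1 library was left out, which argues against the GC trend and against a single library as the cause. A response to electroporated DNA that differed in size between the plasmids stays open. In NULL cells without TGF-beta the same genes had a median change of -0.74 from 24 h to 48 h, which says nothing of the difference between plasmids. That difference was not smaller at 48 h (medians of 0.73 and 0.61) than at 24 h (0.53 and 0.32), and with 1 plasmid per arm a response to DNA cannot be told apart from an effect of the IL-33 protein. The data do not choose between these.

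IL33 was little higher in FLIL33 libraries for an overexpression, with a log2 change of 0.51 ± 0.09 that did not pass the test. The GC trend is not the reason, since the corrected change plus 2 errors is 0.80, below 1. A plasmid label swapped in all 4 pairs stays open. Interferon medians were positive in all 4 pairs (0.32 to 0.73), so a swap in some pairs only would need a response that turned around in those pairs. IL33 was higher in the FLIL33 library in 4 of 4 pairs, but this had been seen before the test and counts only if plasmid transcripts are counted as IL33. Whether transcripts of the plasmid match the counted gene, and what share of cells took it up, was not tested, so the amount of IL-33 made is not known from these counts.

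The effect of TGF-beta differed between times in NTM, by 1.69 on the log2 scale (adjusted p = 0.0168 in edgeR, and 0.0016 after GC correction, with 2 calls on simulated data with no gene changed). By camera, the effect of TGF-beta differed between plasmids in 4 lists, with median log2 differences of -0.14 for the stress response, -0.17 for cholesterol synthesis, -0.20 for contractile genes and 0.49 for BMP and ID genes, and none of these held with an estimated correlation or with fry. For the 3 lists with negative differences, the median TGF-beta effect was smaller in FLIL33 cells at 48 h only, and larger there at 24 h. Single members did not all follow the medians. The difference was negative at both times in 11 of 25 stress response, 7 of 26 contractile and 0 of 22 cholesterol synthesis genes. It was positive at both times in 3, 2 and 1 of them. After GC correction camera also passed for p53 targets (adjusted p = 0.0133), interferon-stimulated genes (0.0351) and endothelial markers (0.0498). No estimated correlation or fry was tried in that setting. Without GC correction each of these lists had adjusted p = 0.702 with an estimated correlation, and fry gave 0.624, 0.853 and 0.853.

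The 8 libraries can be split into 4 and 4 in 35 ways, and an additive model was fitted to each. For TGF-beta 1 of 35 splits, the real one, gave as many as its 4013 genes, and the highest other gave 350. That is the smallest share that 35 splits allow. The other splits leave the TGF-beta effect in their spread, which keeps their counts low (no call in 33 of 35). They thus do not show what chance alone gives, and the splits by themselves do not exclude chance. For FLIL33 the real split gave 8 genes and 4 of 35 splits gave as many, the highest other being 3638. Those 4 include the splits by TGF-beta and by time, real factors that do not bear on chance. A split that crosses the factors also gave as many (1300), so chance cannot be excluded. After GC correction the real split gave 7 genes and again 4 of 35 gave as many, the highest other being 4328. For time the real split gave 2148 genes, and 33 of 35 splits gave no call. As for TGF-beta, the other splits leave the time effect in their spread, so the splits by themselves do not exclude chance. As many genes came from 2 of 35 splits. The highest other, 2442, was the split by TGF-beta, a real factor that does not bear on chance. These other large splits point to a structure of the samples: 3638, 4328 and 2442 came from the split by TGF-beta, 1789 and 2204 from the split by time among the FLIL33 splits, and 1300 and 1364 from 1 split that crosses the factors. The splits by the other factors have 5 residual degrees of freedom and the real split 4. Among the 33 splits with 4, 2 gave as many genes as the real FLIL33 split, that split included, with or without GC correction, and 1, the real one, gave as many as the real time split.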

How the results depend on the processing

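The GC correction and the correlation of effects within 1 time were chosen after the data were seen. No gene called for TGF-beta or for time had the other sign in any setting. The cause of the changes listed here was not tested, except that a stricter threshold, fewer libraries and fewer residual degrees of freedom change counts by construction. With an absolute log2 change of at least 1 as well, the counts were 993 (TGF-beta), 781 (combination), 826 and 724 (TGF-beta in NULL and in FLIL33 cells) and 222 (time). With no time term they were 1910 (TGF-beta), 0 (FLIL33, 476 unadjusted in edgeR), 482 (combination), 674 and 514 (TGF-beta in NULL and in FLIL33 cells). With all 2-way interactions, at 1 residual degree of freedom, they were 5639 (TGF-beta), 1360 (FLIL33), 19 (plasmid by TGF-beta), 574 (TGF-beta by time) and 1018 (plasmid by time). Also at 1 residual degree of freedom, the 24 h libraries alone gave 5600 (TGF-beta) and 464 (FLIL33), and the 48 h libraries alone 1508 (FLIL33). With no filter the counts were 432 (FLIL33), 2541 (combination), 73 and 37 (FLIL33 without and with TGF-beta), 247 (TGF-beta by time) and 780 (plasmid by time). DESeq2 gave 40, 18, 11, 51 and 206 for FLIL33, FLIL33 without and with TGF-beta, TGF-beta by time and plasmid by time. Limma-voom gave 6 (FLIL33) and 1 (plasmid by time), the additive model 8 (FLIL33), DESeq2 size factors 54 (plasmid by time), and the GC correction 3 (FLIL33), 2 (TGF-beta by time) and 0 (plasmid by time).

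Leaving out 1 library at a time gave 2105 to 4102 calls for TGF-beta, 0 to 849 for FLIL33, 0 to 1 for plasmid by TGF-beta, 405 to 2903 for the combination, 560 to 2338 and 510 to 2441 for TGF-beta in NULL and in FLIL33 cells, 0 to 538 and 0 to 6 for FLIL33 without and with TGF-beta, 468 to 2452 for time, 0 to 141 for TGF-beta by time and 0 to 698 for plasmid by time. The correlation of the mean effects turned from -0.147 to 0.0183 in the 48 h libraries alone and lay between -0.197 and -0.119 in the other settings. ANGPTL2, not called for FLIL33 (0.32 ± 0.23), had -0.26 in the 24 h libraries alone. Of 100 list tests, 36 passed by camera and none of them passed with an estimated correlation. The 64 that kept their side of the threshold there had not passed before. That setting passed no list, the lowest adjusted p being 0.0697 for the early targets of TGF-beta, so it does not set one list apart from another. With fry 81 kept their side, with 5 gained and 14 lost, and after GC correction 93 kept it, with 5 gained and 2 lost. The filter removed 10314 of 23682 genes, and whether deeper libraries would have kept more was not tested.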

Other observations

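Some gene groups outside the comparisons told so far moved with time. Of 15 tested genes of IL-33 receptor signalling and type 2 responses 3 rose from 24 h to 48 h (4 adjusted over the list alone). They include the IL-1 receptor gene IL1R1 (0.82 ± 0.11) and TSLP (0.64 ± 0.12). The list had a camera adjusted p of 0.0484 and adjusted p = 0.26 with an estimated correlation. Heat shock genes went down, with 4 of 15 lower (6 adjusted over the list alone), including HSPD1 (-0.38 ± 0.08), and so did BMP and ID genes, with BAMBI (-1.44 ± 0.27) lower over all genes and 2 adjusted over the list alone. Their camera adjusted p-values were 0.0484 and 0.023, with adjusted p = 0.26 with an estimated correlation for each. Of 20 NRF2 targets 3 rose (7 rose and 1 fell adjusted over the list alone), with a camera adjusted p of 0.0484 and adjusted p = 0.598 with an estimated correlation (fry 0.197). Of 23 proteases and inhibitors 5 rose and 1 fell (7 and 3 adjusted over the list alone), up on balance by fry (0.0246) but not past the threshold by camera (0.161). After GC correction the camera adjusted p was 0.145 for NRF2 targets and 0.0503 for the IL-33 receptor list. ABCC9 (-0.83 ± 0.12) was the 1 of 9 pericyte markers that fell (1 adjusted over the list alone, camera adjusted p = 0.0484, and adjusted p = 0.26 with an estimated correlation).

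CTGF, which rose with TGF-beta, fell from 24 h to 48 h (-0.71 ± 0.10), while matrix genes rose over the same time, so this early target and the matrix did not move together. Over the 26 early targets 3 rose and 7 fell with time (5 and 7 adjusted over the list alone, camera adjusted p = 0.393).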
